A study of Arabidopsis thaliana with 4 samples.

How the data were processed

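The series holds 4 RNA-seq libraries made from whole Arabidopsis thaliana seedlings, 2 labelled wild type (WT) and 2 labelled fer-4, a mutant of the receptor kinase gene FERONIA (FER). Per the labels, all seedlings were of the Col-0 ecotype, were 7 days old, had been raised on upright plates of diluted Murashige and Skoog medium in 16 h of light and 8 h of darkness, and had received no treatment. Total RNA was made into libraries with an mRNA-seq kit, per the labels' protocols. The labels number the replicates 1 and 2 within each genotype. They do not say whether replicates came from separate plates, seed lots or days, so the p-values below measure only the spread between these libraries, which may be technical.

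The values are gene-level FPKM (fragments mapped to a gene, scaled by its length and by the mapped fragments of the library), as the authors deposited them, with 1 file per library; the unit is named in the file headers. The submitters' processing notes name CASAVA, HISAT2 2.0.5, StringTie 1.3.3 and the genome build TAIR10, without roles, order or settings. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without a known strand setting, the values of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are named below as uncertain. Of the genes named in the text, these share a locus in the files with another gene or overlap one in the annotation, mostly on the other strand, and their values are uncertain for that reason: AT1G25098, AT4G34881, AT3G60950, EDS5, COR15B, BZR2, CKX5, CESA4, CESA8, EXPA7, UGT75C1, LHCB4.2, LHCB6, CASP5, CYCD3-1, CDKB2-2, FRO3, BHLH101, AT2G30766, F6'H1, ELF3, DREB2A, HSP17.4A, SBE2.1, PAO, UGT76E12, PYK10, JAL34, BCAT2, MCCA, IVD, DIN10, ADH1, AT4G13860, AT1G24800, AT1G25211 and CPuORF35.

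Each file lists only genes with an FPKM above 0, so a gene missing from a file was set to 0. The files listed 22537 and 22652 genes in WT replicates 1 and 2 and 22844 and 22747 in fer-4 replicates 1 and 2. Together they listed 24252 genes, 21290 of them in all 4 libraries. Of the 2962 genes missing from at least 1 file, 106 reached 5 FPKM or more in another library. Gene identifiers were matched to the RefSeq annotation of TAIR10.1, which gave names, descriptions and positions for 24039 genes, and 213 identifiers had no match. Positions in the text come from TAIR10.1.

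The files hold no fragment counts. Among genes with a single transcript longer than 1000 bp, the smallest listed values clustered near 50.9 FPKM times bp in WT replicate 1, 50.4 in WT replicate 2, 48.0 in fer-4 replicate 1 and 51.3 in fer-4 replicate 2, which was read as the value of 1 fragment. On that reading the libraries held about 19.7, 19.8, 20.8 and 19.5 M fragments, and 1 FPKM in a transcript of 1500 bp stood for 29.2 to 31.3 fragments. These depths are estimates. The FPKM of a library summed to between 680752 and 689279.

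Values were compared as log2(FPKM + 1) with the limma-trend method (limma 3.58.1 in R 4.3.3; lmFit and eBayes with a mean-variance trend) between the genotypes, without covariates. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes on this scale understate the change of genes with low values, so ratios of mean FPKM are given beside them. An exact permutation test of 2 libraries against 2 is of no use at this threshold, since the smallest share of splits it can reach is 33.3%. Errors of FPKM are standard deviations over 2 libraries, and errors of log2 fold changes are limma's moderated standard errors. All p-values are two-sided unless stated.

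Before the data were examined, 32 gene lists with 595 genes and 28 gene families defined by words in the gene descriptions were fixed, together with the design and the alternatives. List members whose identifier carries another symbol in the annotation, with the symbol of the list not among its synonyms, were dropped (8 memberships). Lists with at least 3 tested members and families with at least 5 were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes. The seed storage list, a marker of embryo tissue, had too few tested members. FER was left out of the lists. Beside camera, the same test with a correlation estimated from the data, and fry, were run. The description patterns of 3 families were limited to whole words after the data were seen, because as written they also took in the words superfamily, methionine and germination.

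The genes named were chosen by a rule fixed before the data were examined. FER came first. Then came the 10 largest rises and the 10 largest falls in log2 fold change among genes past the threshold whose fer-4 libraries both lay outside the WT range. In each list up to 4 members past the threshold were taken, the 2 largest rises and the 2 largest falls, with more of the other direction where 1 was short. In a list with no such member, the 2 members with the smallest p were taken. Of each family named, up to 3 members were taken in the same order. Near-identical copies were to be named as uncertain. Other genes are said to have been chosen after their values were seen.

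The gene test was checked on simulated libraries for the fer-4 and WT comparison, over 19183 genes. It recovered 41 of 67 genes changed 1.5-fold, 60 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 9 false calls. The simulated spread differed less from gene to gene than the fit to the real libraries estimated, so recovery there may be lower. Camera at the preset correlation called a simulated list of 25 genes shifted by 0.6 on the log2 scale and called 0 of 30 unshifted lists. The simulated genes varied independently of each other, so this does not show how camera fares on lists whose members vary together. In the real libraries the estimated correlation was 0.67 in the jasmonate response list and 0.90 in the iron deficiency list. With an estimated correlation that shifted list had an adjusted p of 0.63, and with fry 0.183, so these tests missed a known shift of that size with 2 libraries in each group.

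The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter on low values or a minimum mean of 5 FPKM, rescaling to TPM, median-ratio scaling, quantile normalization, eBayes without a trend or with robust settings, the replicate number as a block, and each library left out in turn. With 1 library left in a genotype, limma takes the spread from the other genotype, so that the lone library is assumed to vary like the others. Added after the data were seen were fits without the genes close to absent from 1 genotype, fits on genes listed in every library, and a block with crossed replicate numbers. Tables were joined and further tests and plots made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.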

Results

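Whole-seedling mRNA of 7-day-old Arabidopsis was profiled in 2 WT and 2 fer-4 libraries, to compare the transcripts of WT seedlings with those of a mutant of FERONIA, a receptor kinase that senses the cell wall and binds RALF peptides. Gene levels are given in FPKM as the authors deposited them. By the estimate from the smallest listed values, the libraries held about 19.5 to 20.8 M fragments each. The groups did not overlap in 66.1% of the tested genes, against 33.3% by chance. Spearman correlations across genes were 0.992 between the WT libraries, 0.990 between the fer-4 libraries and 0.950 to 0.960 between genotypes; genes are not independent replicates.

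In the fer-4 libraries the lists of jasmonate synthesis and response, ethylene-branch defence with the PDF1 defensins, iron deficiency, glucosinolates and senescence shifted to higher transcript levels. The joint list of expansins and xyloglucan-modifying enzymes, the primary wall cellulose synthases, the arabinogalactan proteins, the pectin methylesterases with their inhibitors and the photosynthesis genes shifted to lower levels. These groups passed camera at its preset correlation; with an estimated correlation 0 passed (adjusted p = 0.95 for the lists and adjusted p = 0.791 for the families), and with fry 0 passed. Several also did not pass under other alternatives, which are given with each group. The jasmonate synthesis gene AOC1 rose 6.63-fold, from 40.5 ± 9.85 to 268 ± 69.6 FPKM (SD, n = 2). The wall gene CESA5 fell from 44.4 ± 2.78 to 22.8 ± 1.68 FPKM, and the floral activator FT fell from 4.73 ± 0.0852 to 0.421 ± 0.0958 FPKM. In addition, 158 genes were present in 1 genotype and nearly absent from WT replicate 1 or from both fer-4 libraries. These genes leave open that the lines compared differ in genetic background. In that case any difference given here may reflect the lines and not the mutation.

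FER itself (AT3G51550, TAIR10.1 chromosome 3, 19117584 to 19120949, minus strand, protein-coding) measured 89.0 and 91.9 FPKM in WT and 60.6 and 62.1 FPKM in fer-4, so transcript from the locus was still present in the mutant. Its log2 fold change was -0.55 ± 0.08 (SE; limma, adjusted p = 0.00638), a WT mean 1.47 times the fer-4 mean. A gene-level FPKM does not show whether a transcript is intact, and the position of the insertion or lesion is not given in the sources used here. Without WT replicate 2 the change was -0.53 with an adjusted p of 0.0593, the highest over the alternatives, which began at 0.00566.

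Among the 13 tested relatives in the FERONIA receptor family, 2 rose and 2 fell (2 and 3 adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.947), whose direction was down although the list median was 0.08 (-0.24 to 0.11 over the alternatives). THE1, which encodes THESEUS1, a sensor of cellulose damage, fell from 45.2 ± 3.72 to 26.8 ± 1.19 FPKM (log2 fold change -0.73 ± 0.10, adjusted p = 0.00416), and the kinase gene AT5G24010 fell from 7.82 ± 0.0358 to 5.19 ± 0.252 FPKM. The kinase genes AT5G39030 and AT5G39020 rose from 0.115 ± 0.0731 to 3.15 ± 0.752 and from 0.773 ± 0.0259 to 3.98 ± 0.538 FPKM. Of 8 RALF peptide genes, 3 fell and 1 rose (3 and 2 adjusted over the list alone; camera adjusted p = 0.359). RALF23, a ligand of FERONIA, fell from 81.0 ± 4.30 to 43.9 ± 7.49 FPKM, RALFL33 from 95 ± 8.71 to 53.5 ± 5.93 and RALFL22 from 83.6 ± 3.82 to 47.8 ± 1.05, while RALFL27 rose from 0.555 ± 0.557 to 6.33 ± 0.481. Among 17 signalling partners, ROPGEF1, LRX4 and ARAC4 (ROP2) fell by 0.43, 0.42 and 0.32 on the log2 scale (2 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.26). These 3 calls and that of AT5G24010 ended without either WT library, and those of RALF23 and RALFL33 ended without WT replicate 2.

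Of 19183 genes tested, 2743 were higher and 1726 lower in fer-4, 4469 in all, and 7210 had an unadjusted p under 0.05. A change of at least 2-fold was found in 1010 higher and 320 lower genes. Higher genes made up 61.4% of the calls, but quantile normalization gave 2285 higher and 2364 lower genes, 49.2% higher, so the excess of rises depended on the scaling. Without WT replicate 1 the count was 1905 (1373 higher, 532 lower) and without WT replicate 2 it was 1688 (1227 higher, 461 lower).

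The largest rises were those of ECS1, TGG2, PDF1.2C, HR4, PDF1.3, AT1G25098, AT4G34881, QQS, JAL33 and PDF1.2A, with log2 fold changes from 5.84 (PDF1.2A) to 7.21 (ECS1). ECS1 (AT1G31580, chromosome 1, 11310997 to 11311989) went from 4.63 ± 6.55 to 476 ± 58.5 FPKM (7.21 ± 0.98, adjusted p = 0.00473). TGG2 (AT5G25980, chromosome 5, 9072708 to 9075777), a myrosinase that breaks down glucosinolates, went from 5.61 ± 6.03 to 565 ± 38.9 FPKM (6.80 ± 0.64, adjusted p = 0.00136). QQS, a gene that affects starch content, was listed in neither WT library and measured 68.1 and 49.2 FPKM in fer-4. HR4, a homolog of the RPW8 mildew resistance genes, measured 0.333 and 2.51 FPKM in WT and 104 and 191 FPKM in fer-4. The jacalin-related lectin gene JAL33 went from 3.35 ± 2.12 to 237 ± 38.6 FPKM. PDF1.2A, PDF1.2C and PDF1.3 are near-identical copies, so how reads divide among them is uncertain, and AT1G25098 and AT4G34881 overlap other genes.

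The largest falls were those of AT2G05914, AT2G15555, ESP, AT5G33251, LTP4, AT4G19240, AT3G28320, AT4G24420, AT3G60950 and AT4G15242, from -7.01 (AT2G05914) to -4.04 (AT4G15242) on the log2 scale. ESP (AT1G54040, chromosome 1, 20170715 to 20173949), the epithiospecifier protein that diverts glucosinolate breakdown toward nitriles, measured 419 and 419 FPKM in WT and 3.95 and 5.91 FPKM in fer-4 (-6.16 ± 0.16, adjusted p = 5.53e-05). The lipid transfer protein gene LTP4 fell from 31.5 ± 0.92 to 0.637 ± 0.472 FPKM. AT2G05914 and AT2G15555, annotated as other RNA, fell from 166 ± 16.5 to 0.292 ± 0.109 and from 107 ± 2.37 to 0.0343 ± 0.0486 FPKM. AT5G33251, AT4G19240, AT3G28320, AT3G60950 and AT4G15242 were listed in neither fer-4 library, and AT3G60950 lies in a locus shared with another gene.

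All 20 of these genes met a rule set after the data were seen, by which 141 genes had at least 5 FPKM in both fer-4 libraries but under 5% of the fer-4 mean in WT replicate 1, and 17 had at least 5 FPKM in both WT libraries but under 5% of the WT mean in both fer-4 libraries. These 158 genes are called all-or-none here, and the 141 fer-4-only, but the rule sets no limit for WT replicate 2, where 115 of the 141 were also under 5% of the fer-4 mean. CPuORF35, chosen after its values were seen, measured 5.43 FPKM in WT replicate 2, 75.1% of its fer-4 mean, and was not called. The other 157 genes were among the calls. They lay on all 5 chromosomes, with 48, 23, 28, 25 and 33 genes on chromosomes 1 to 5. On chromosome 1, 10 fer-4-only genes lay between 8769511 and 8837007, from AT1G24800 to AT1G25211. Several of them share the description F-box family protein, and others that of a deacetylase family. They may be similar copies, so how reads divide among them, and with it the count of 10, is uncertain. The disease resistance family had 15 members among the 158 (9.49%), against 114 of the 19183 tested genes (0.59%, Fisher's exact test, p = 2.87e-14). The test counts each member singly, although such genes form clusters of similar copies, so its p overstates the evidence. Without the 158 genes, 2626 genes were higher and 1734 lower.

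**Figure D1:**
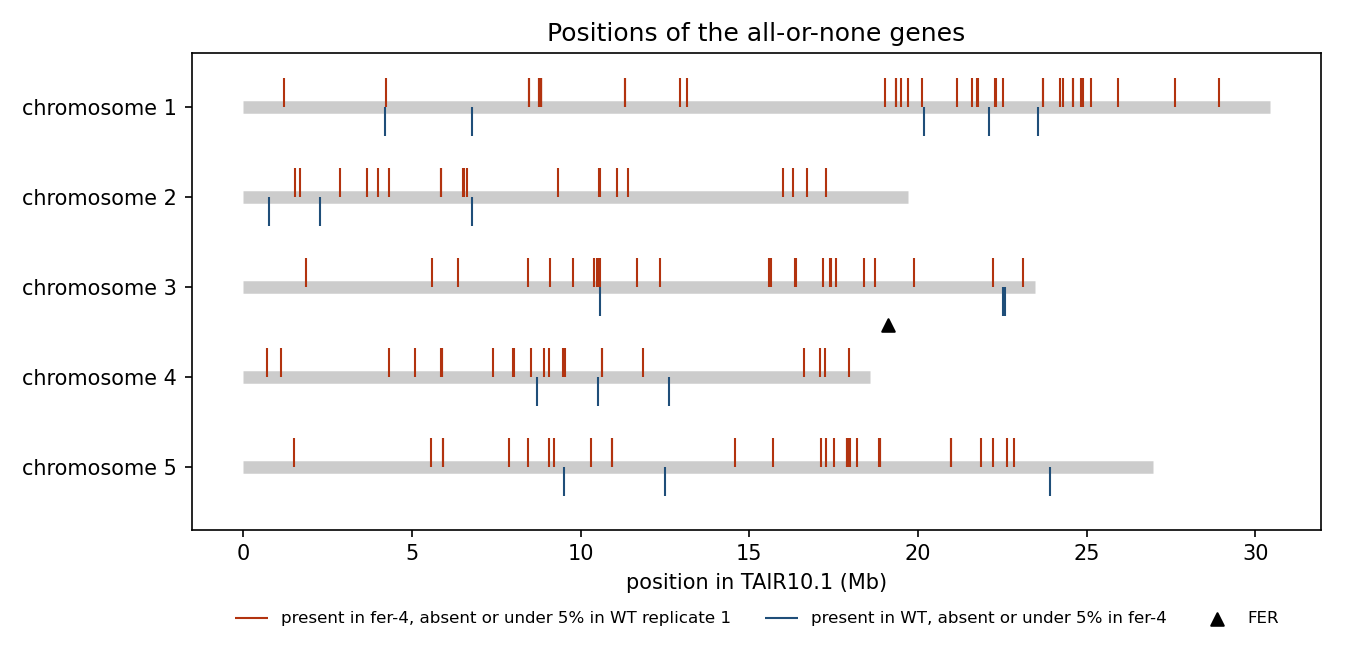
Positions of 157 of the 158 all-or-none genes (1 has no nuclear position) along the 5 chromosomes of TAIR10.1, in Mb. Red marks stand for genes present in fer-4 and under 5% of that level in WT replicate 1, and blue marks for genes present in WT and under 5% in both fer-4 libraries; the triangle marks FER on chromosome 3, and the genes lie on all 5 chromosomes.

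The WT libraries differed in these genes. Of the 141 fer-4-only genes, 67 were not listed in WT replicate 1 but only 9 were not listed in WT replicate 2. Among the 98 with a ratio between the fer-4 libraries from 0.8 to its inverse, the median level in WT replicate 2 was 3.26% of that in fer-4 replicate 1 (interquartile range 2.49% to 4.5%), against 0% in WT replicate 1 (0% to 0.73%). These genes were chosen for a low level in WT replicate 1. Of 131 genes chosen instead on the mean of both WT libraries, 66 were not listed in WT replicate 1 and 9 not in WT replicate 2, and the 92 steady ones had medians of 0% (0% to 0.47%) and 3.09% (2.42% to 4.22%). ECS1, for example, was not listed in WT replicate 1 and measured 9.27 FPKM in WT replicate 2.

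**Figure D2:**
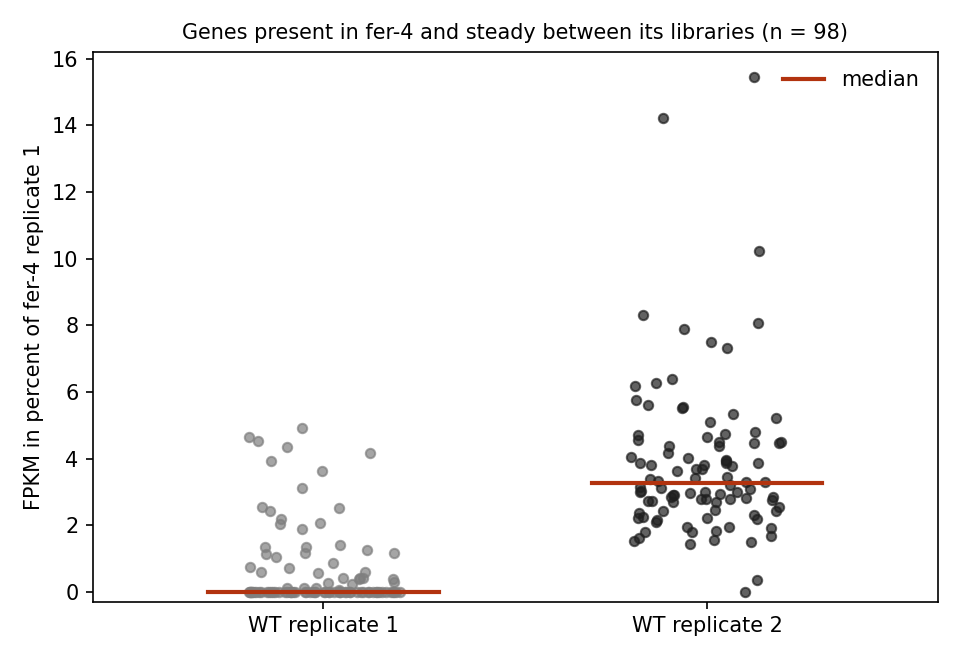
Level of 98 fer-4-only genes in WT replicates 1 and 2, in percent of their FPKM in fer-4 replicate 1 (1 point per gene, line at the median). The median is 0% in WT replicate 1, on whose low level the genes were chosen, and 3.26% in WT replicate 2.

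Of 13 tested jasmonate biosynthesis genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a list median of 0.97 on the log2 scale, 0.74 to 1.26 over the alternatives (camera adjusted p = 1.61e-05, and adjusted p = 0.95 with an estimated correlation). AOC1 and AOC2, neighbouring allene oxide cyclase genes of similar sequence, rose 6.63-fold and 5.78-fold, the lipoxygenase gene LOX3 rose 3.59-fold (9.70 ± 2.28 to 34.8 ± 6.35 FPKM) and OPR3, which reduces the jasmonate precursor OPDA, rose 2.61-fold (56.3 ± 3.1 to 147 ± 7.06 FPKM, adjusted p = 0.0005). Of 24 jasmonate response genes, 16 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 1.31, 0.84 to 1.69 over the alternatives (camera adjusted p = 1.11e-07, and adjusted p = 0.95 with an estimated correlation). The chlorophyllase gene CLH1 rose 13.6-fold, from 14.7 ± 0.384 to 199 ± 64.8 FPKM, and the storage protein gene VSP2 rose 7.30-fold, from 12 ± 2.83 to 87.4 ± 21 FPKM. TAT3, a tyrosine aminotransferase gene, measured 0.994 and 0.292 FPKM in WT and 13.2 and 90.0 FPKM in fer-4. The repressor gene TIFY 5B (JAZ7) fell from 14.2 ± 1.06 to 8.99 ± 1.74 FPKM. The calls of TAT3 and TIFY 5B ended without either WT library.

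Of 21 ethylene and ERF-branch defence genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.000353), with an adjusted p = 0.95 with an estimated correlation. PDF1.2A measured 3.42 and 1.38 FPKM in WT and 85.7 and 398 FPKM in fer-4, PDF1.2C 0.378 and 0 against 45.8 and 232, and PDF1.3 0.226 and 0 against 20.5 and 224. HEL, which encodes the chitin-binding protein PR4, rose 3.08-fold, from 132 ± 12.2 to 406 ± 245 FPKM (adjusted p = 0.0436). The wider family of plant defensins and thionins had 11 of 18 members higher and 0 lower (12 and 0 adjusted over the list alone; camera adjusted p = 1.55e-05, and adjusted p = 0.791 with an estimated correlation). With the description pattern as first written, which also took in the word methionine, 37 of 180 genes were higher and 13 lower and the family did not pass (adjusted p = 0.541).

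The fer-4 libraries differed in these genes. In replicate 2 against replicate 1 the median member was higher by 0.51 on the log2 scale in the jasmonate response list, 0.44 in jasmonate biosynthesis and 0.39 in ethylene-branch defence, while the median over all tested genes was 0.013. The calls of PDF1.3 and HEL ended without either WT library.

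**Figure D3:**
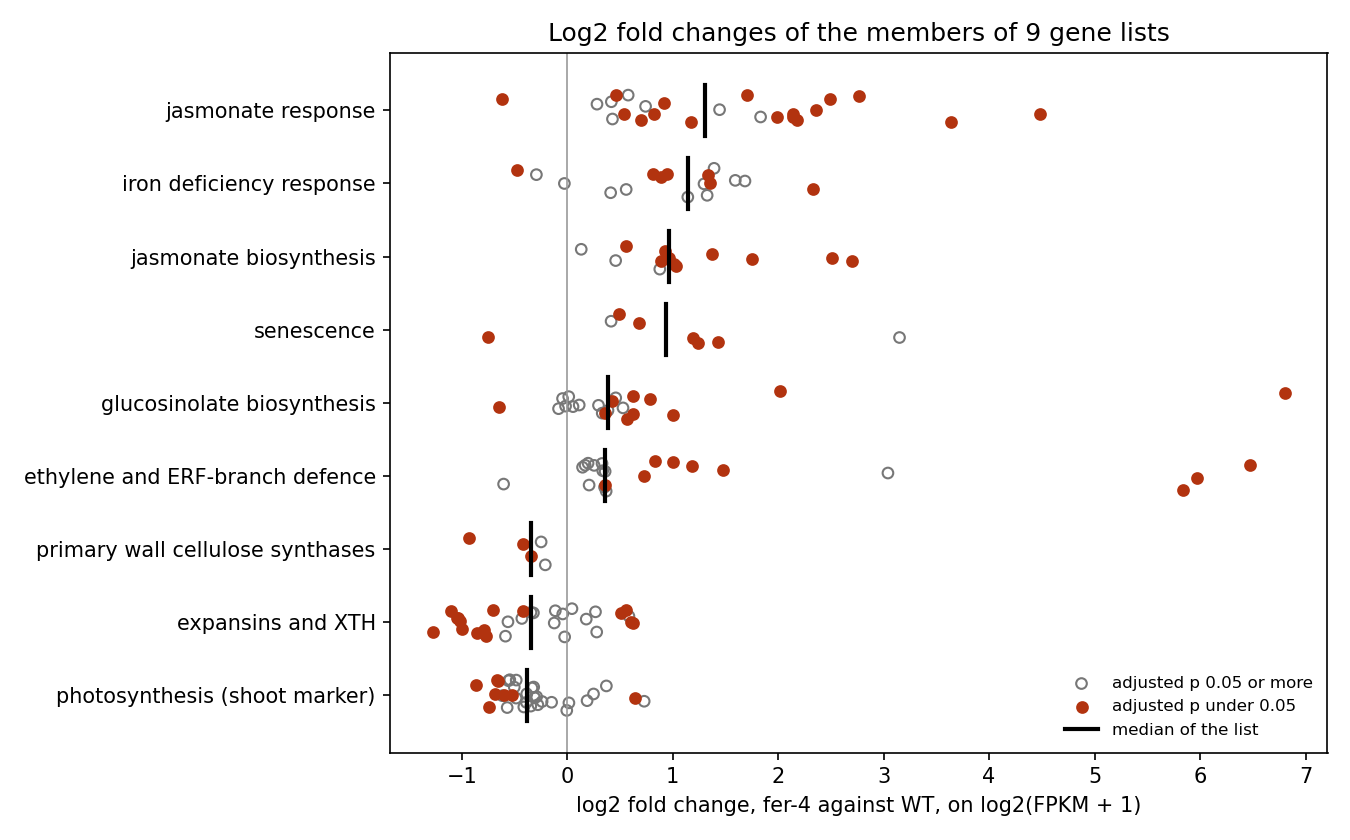
Log2 fold changes, fer-4 against WT on log2(FPKM + 1), of the tested members of the 9 lists past the camera threshold. Filled points passed the gene test at an adjusted p under 0.05, open points did not, and black lines mark list medians, from 1.31 in the jasmonate response list to -0.38 in photosynthesis.

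Genes of salicylic acid and systemic immunity went both ways. Of 20 tested, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.8). BG2, the glucanase PR2, rose from 0.977 ± 0.634 to 20.2 ± 14.1 FPKM and EDS5, a salicylate transporter, from 7.66 ± 0.335 to 20.7 ± 4.06 FPKM. ALD1, needed for the systemic signal pipecolic acid, fell from 6.54 ± 0.244 to 1.04 ± 0.418 FPKM (-1.90 ± 0.18, adjusted p = 0.0013), and WRKY70 from 45.8 ± 1.41 to 18.8 ± 6.71 FPKM. PR1, chosen after its values were seen, measured 2.48 and 0.512 FPKM in WT and 4.88 and 82.4 FPKM in fer-4 and did not pass (adjusted p = 0.0954). In the salicylic acid list the median member was higher by 0.58 in fer-4 replicate 2 than in replicate 1.

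Of 24 pattern-triggered immunity genes, 9 rose and 2 fell (11 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0955). CYP71A12 and CYP71B15 (PAD3), enzymes of camalexin synthesis, measured 18.5 ± 13.9 and 36.1 ± 31.3 FPKM in fer-4 against 1.55 ± 0.426 and 4.67 ± 0.967 in WT, and the kinase gene MPK3 fell from 239 ± 14.3 to 173 ± 17.1 FPKM and WRKY22 from 14.8 ± 0.531 to 11 ± 1.14. This list passed with the replicate block (adjusted p = 0.0343) and without fer-4 replicate 1 (0.00788), in a range up to 0.369 over the alternatives. The calls of CYP71A12, CYP71B15, MPK3, WRKY22 and WRKY70 ended without either WT library, and that of BG2 without WT replicate 2.

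Disease resistance proteins, mostly intracellular NLR receptors, had 56 of 114 genes higher and 10 lower (57 and 11 adjusted over the list alone; camera adjusted p = 5.66e-07, and adjusted p = 0.791 with an estimated correlation). The largest rises, of WRR4 (1.03 ± 1.46 to 44.4 ± 14.5 FPKM), AT1G63880 (0.455 ± 0.643 to 23.4 ± 5.18) and AT4G19510 (0.347 ± 0.455 to 19.7 ± 2.52), belonged to the all-or-none genes. Without the 15 all-or-none members, 41 of 99 were higher and 10 lower. NLR genes form clusters of similar copies, so single members are uncertain.

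Of 21 tested glucosinolate genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00974, and adjusted p = 0.95 with an estimated correlation). MAM1, which elongates methionine for aliphatic glucosinolates, rose 4.26-fold, to 74.9 ± 16.4 FPKM in fer-4 (2.02 ± 0.16, adjusted p = 0.000784). CYP79B3, which opens the indolic branch, rose 2.05-fold, from 35.3 ± 4.12 to 72.1 ± 16 FPKM, whereas CYP79F1 of the aliphatic branch fell from 15.4 ± 2.01 to 9.59 ± 2.24 FPKM. The largest rise in the list was that of TGG2, which degrades glucosinolates and belongs to the all-or-none genes. In fer-4 replicate 2, 18 of the 21 were higher than in replicate 1, with a median of 0.30. The list did not pass without fer-4 replicate 2 (adjusted p = 0.114, the highest over the alternatives, which began at 0.000184), and the calls of CYP79B3 and CYP79F1 ended without either WT library.

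Several groups of cell wall genes had more falls than rises in fer-4. Of 29 expansin and xyloglucan endotransglucosylase (XTH) genes, 11 fell and 4 rose (11 and 5 adjusted over the list alone; camera adjusted p = 0.0293, and adjusted p = 0.95 with an estimated correlation). XTH18 fell from 97.7 ± 2.35 to 40.1 ± 6.32 FPKM (-1.27 ± 0.12, adjusted p = 0.0014) and XTH20 fell 2.29-fold, to 13.1 ± 1.83 FPKM, whereas EXPA1 rose from 74.9 ± 13.4 to 115 ± 19.6 FPKM and XTH31 from 16.8 ± 2.17 to 26.3 ± 5.10 FPKM. The expansin family alone had 4 of 22 genes higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.349), and extensins and proline-rich wall proteins 28 of 147 lower and 17 higher (29 and 18 adjusted over the list alone; camera adjusted p = 0.23). Of 5 primary wall cellulose synthases, 3 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.95 with an estimated correlation). CESA5 fell by 0.93 ± 0.10 on the log2 scale (adjusted p = 0.00182), CESA2 by 0.41 and CESA6 by 0.34. Of 9 secondary wall and xylem genes, 0 passed by limma at either adjustment, over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.779). CESA4 and CESA8 measured 8.86 ± 0.638 and 6.48 ± 1.02 FPKM in fer-4 against 6.47 ± 0.676 and 4.54 ± 0.493 in WT (adjusted p = 0.0585 and 0.0819). The expansin and XTH list did not pass without WT replicate 1 (adjusted p = 0.0677), without a filter (0.0715) or after quantile normalization (0.103), in a range from 0.0106 over the alternatives. The calls of EXPA1, XTH31, CESA2 and CESA6 ended without either WT library, and that of XTH20 without WT replicate 1.

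Arabinogalactan proteins, proteoglycans of the cell surface, had 23 of 42 genes lower and 1 higher (27 and 1 adjusted over the list alone; camera adjusted p = 5.66e-07, and adjusted p = 0.791 with an estimated correlation). AGP17 fell 3.59-fold, from 39.7 ± 3.44 to 11 ± 0.49 FPKM (adjusted p = 0.000317), and AGP15 from 808 ± 87.7 to 347 ± 37.1 FPKM. AGP14, the exception, rose 7.44-fold, from 4.78 ± 0.488 to 35.6 ± 1.23 FPKM. Pectin methylesterases and their inhibitors had 13 of 47 genes lower and 3 higher (14 and 6 adjusted over the list alone; camera adjusted p = 0.0392, and adjusted p = 0.791 with an estimated correlation). PME7 fell from 40.8 ± 2.13 to 16.3 ± 3.26 FPKM and PME41 from 30 ± 0.0793 to 12.8 ± 1.64 FPKM, and the inhibitor-related gene AT5G62360 rose from 13.2 ± 4.38 to 47.3 ± 2.42 FPKM. The pectin family did not pass without WT replicate 1 (adjusted p = 0.121), without fer-4 replicate 1 (0.0855), without a filter (0.197), at a minimum of 5 FPKM (0.099) or after quantile normalization (0.0657), in a range from 0.00602 over the alternatives.

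Of 32 photosynthesis genes, taken as shoot markers, 7 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.38 on the log2 scale, -0.61 to -0.22 over the alternatives (camera adjusted p = 0.00123, and adjusted p = 0.95 with an estimated correlation). The photosystem I genes PSAF and PSAG fell from 857 ± 41 to 475 ± 113 and from 980 ± 78.5 to 612 ± 113 FPKM and the antenna gene LHCB6 from 347 ± 6.01 to 209 ± 41.7 FPKM, whereas LHCB4.2 rose from 65.8 ± 0.53 to 104 ± 17.7 FPKM. In fer-4 replicate 2 the median photosynthesis gene was 0.39 below replicate 1, and 1 of the 32 was higher there. The list did not pass without fer-4 replicate 2 (median -0.22, adjusted p = 0.114) or after quantile normalization (median -0.23, adjusted p = 0.17), in a range from 1.07e-07 over the alternatives, and the calls of these 4 genes ended without either WT library.

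Of 20 root markers, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.737). BGLU22 rose from 87.0 ± 14.5 to 205 ± 71.8 FPKM and TIP2-3 from 5.56 ± 0.385 to 13 ± 1.16, while NRT2.1 fell from 2.5 ± 0.86 to 0.762 ± 0.052 and CASP5 from 7.66 ± 1.47 to 3.73 ± 1.13. Of 9 cell division genes, taken as meristem markers, 2 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.254), with the cyclin gene CYCB1-4 at 7.89 ± 0.242 FPKM against 4.86 ± 0.231 in WT, CYCD3-1 at 22.3 ± 1.39 against 30.4 ± 0.287 and CDKB2-2 at 14 ± 0.951 against 18.4 ± 1.1. Of 32 root hair genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.779). EXPA7 rose from 8.25 ± 0.203 to 12.1 ± 0.568 FPKM, PER60 from 5.98 ± 0.259 to 8.89 ± 0.475, and XTH12 fell from 7.84 ± 0.76 to 4.43 ± 0.41. Of these genes, the calls of EXPA7, PER60, XTH12, BGLU22, CASP5, CYCB1-4, CYCD3-1 and CDKB2-2 ended without either WT library, and that of NRT2.1 ended without WT replicate 1.

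Of 8 senescence genes, regulators and enzymes of chlorophyll breakdown among them, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.95 with an estimated correlation). The transcription factor genes ATNAC2.1 (ORE1) and NAC029 (NAP) rose from 2.54 ± 1.04 to 8.42 ± 1.53 and from 0.337 ± 0.1 to 2.06 ± 0.366 FPKM. PAO, which opens the chlorophyll ring during breakdown, rose 2.46-fold, and NYC1, a chlorophyll b reductase gene, fell from 113 ± 15.9 to 67.3 ± 11.6 FPKM. In fer-4 replicate 2 the median member was 0.23 above replicate 1. The list did not pass without a filter (adjusted p = 0.0729) or at a minimum of 5 FPKM (0.0503), in a range from 0.00291 over the alternatives, and the call of NYC1 ended without either WT library. Among 18 starch and sugar genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.76). ASN1, an asparagine synthetase induced in darkness and low sugar, rose 13.3-fold, from 4.32 ± 0.222 to 57.6 ± 1.24 FPKM (3.46 ± 0.09, adjusted p = 5.53e-05), and STR15 (SEN1), also induced by darkness, rose 4.28-fold, while SBE2.1 and DPE1 fell by 0.51 and 0.32 on the log2 scale, calls that ended without either WT library.

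**Figure D4:**
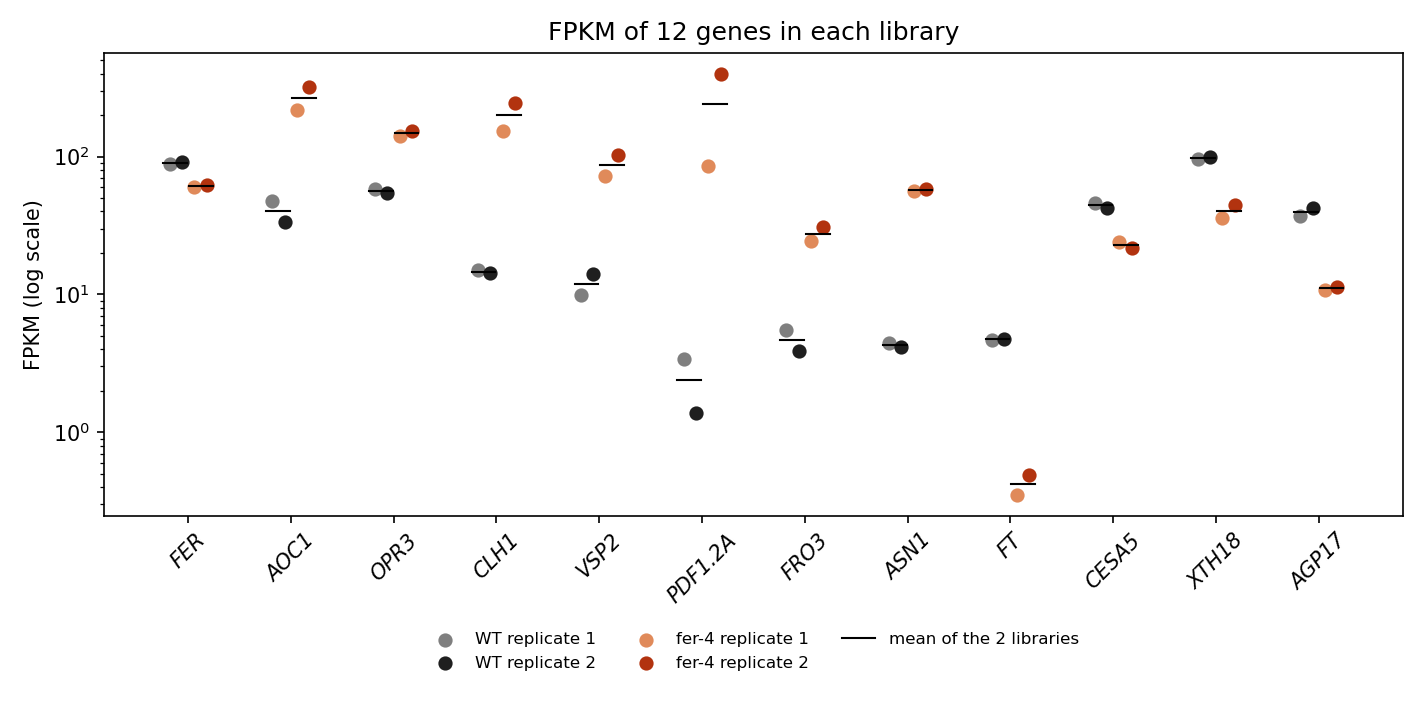
FPKM of 12 genes in each of the 4 libraries on a log scale, with lines at the mean of each genotype. The fer-4 libraries lie above both WT libraries for AOC1, OPR3, CLH1, VSP2, PDF1.2A, FRO3 and ASN1 and below both for FER, FT, CESA5, XTH18 and AGP17.

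Of 17 iron deficiency genes, 6 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 1.14 on the log2 scale, 0.54 to 1.58 over the alternatives, and a camera adjusted p of 0.0113 (adjusted p = 0.95 with an estimated correlation). FRO3, a ferric reductase gene, rose 5.85-fold, from 4.70 ± 1.11 to 27.5 ± 4.64 FPKM (2.33 ± 0.18, adjusted p = 0.000661). BHLH101, a regulator of the iron response, rose from 0.372 ± 0.526 to 2.42 ± 0.745 and AT2G30766 from 22.7 ± 5.96 to 59.9 ± 21.8 FPKM, and F6'H1, of coumarin synthesis, fell from 38.8 ± 0.369 to 27.6 ± 1.1 FPKM. All 17 were higher in fer-4 replicate 2 than in replicate 1 (median 0.53), and in WT the median was -0.52. The list did not pass at a minimum of 5 FPKM (adjusted p = 0.0998, the highest over the alternatives, which began at 6.61e-05), and the calls of F6'H1 and AT2G30766 ended without either WT library and that of BHLH101 without WT replicate 2. Of 11 phosphate starvation genes, the ribonuclease gene RNS1 rose 4.39-fold and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.26), but without WT replicate 2 the list passed as lower (adjusted p = 0.000405, with a range up to 0.797 over the alternatives).

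Flowering time genes went both ways. Of 27 tested, 7 rose and 5 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.8, with a list median of -0.04 but a mean of 0.06). FT (AT1G65480) fell 11.2-fold (-2.01 ± 0.15, adjusted p = 0.000648) and SOC1 fell 2.80-fold, from 21.2 ± 3.81 to 7.58 ± 1.36 FPKM. FLC rose from 0.549 ± 0.161 to 3.78 ± 0.447 FPKM (1.63 ± 0.17, adjusted p = 0.00182), and MAF4 was listed in neither WT library and measured 2.96 and 2.18 FPKM in fer-4. Of 14 circadian clock genes, 2 fell and 1 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.779). APRR3 fell 2.09-fold, to 8.52 ± 0.154 FPKM, and TCP21 (CHE) from 25.7 ± 0.534 to 13.1 ± 1.16 FPKM, and ELF3 rose from 29.1 ± 1.94 to 37.6 ± 3.11 FPKM, a call that ended without any 1 of WT replicate 1, WT replicate 2 or fer-4 replicate 1.

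Abscisic acid and cold genes went both ways. Of 22 abscisic acid genes 6 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.779). NAC072 rose from 3.13 ± 0.786 to 21.4 ± 3.19 FPKM and the dehydrin gene XERO2 from 12.4 ± 1.5 to 38.9 ± 4.18, while CYP707A2, which breaks down abscisic acid, fell from 3.92 ± 0.964 to 0.935 ± 0.026 and RD22 from 55.0 ± 4.81 to 24.6 ± 0.989. Of 13 cold genes 5 fell and 3 rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.359), with COR15A down from 93.2 ± 4.06 to 25.6 ± 7.69, COR15B down from 62.7 ± 1.04 to 32.8 ± 7.18 and KIN1 up from 20.7 ± 1.01 to 33 ± 2.7 FPKM. The call of COR15B ended without either WT library and that of KIN1 without WT replicate 1.

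No growth hormone list passed camera. For auxin, 2 of 23 rose and 2 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.779), with GH3.3 and IAA2 up by 1.13 and 0.74 and SAUR66 and YUC9 down by -1.05 and -0.60 on the log2 scale. For brassinosteroids, 2 of 12 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.947), with IBH1 up 2.98-fold, ROT3 up 1.57-fold, and BZR2 and the receptor gene BRI1 down by -0.60 and -0.34. For gibberellins, 2 of 11 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.779), with GASA6 down from 332 ± 27.1 to 116 ± 55 FPKM, GA2OX2 down by -0.46, and GASA4 and GA2OX6 up by 0.64 and 0.70. For cytokinin, limma called 0 of 11 at either adjustment, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.836), and ARR7 and CKX5 had adjusted p of 0.184 and 0.2, though ARR7 passed with the replicate block (0.0308) and CKX5 without fer-4 replicate 1 (0.0173). Without either WT library the calls of SAUR66, YUC9, ROT3, BZR2, BRI1, GASA6, GA2OX2 and GA2OX6 ended, and without WT replicate 2 also those of GH3.3 and GASA4.

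In the remaining lists, 4 of 17 anthocyanin and flavonoid genes rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.779). A3G2XYLT, UGT75C1 and 3AT2 rose 2.09-fold, 1.75-fold and 1.62-fold and BHLH2 (EGL3) fell from 5.30 ± 0.0629 to 2.96 ± 0.0418 FPKM. Of 9 phenylpropanoid genes PAL1 rose 1.29-fold and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.76). Of 11 heat shock genes DREB2A and HSP17.4A rose 1.86-fold and 2.35-fold and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.75). The calls of these 7 genes ended without either WT library. Of the 134 genes named by the rule for the groups and the extremes, 56 lost their call without WT replicate 1 and 59 without WT replicate 2, and none reversed. Calls were also lost for 26 of them without a filter, 22 without fer-4 replicate 2, 14 without fer-4 replicate 1, 15 without a variance trend, 13 with the replicate block and 9 after quantile normalization. Robust variance ended 10 calls (ARAC4, AT1G25098, AT2G30766, AT4G34881, CYP71A12, CYP71B15, ECS1, HEL, PDF1.3 and TAT3), and median-ratio scaling 5 (ARAC4, ELF3, EXPA1, GA2OX2 and HEL). Rescaling to TPM and a pseudocount of 0.1 FPKM ended 3 calls each. A minimum of 5 FPKM ended 1, and not all of the 134 genes were tested there. Except for ECS1, AT1G25098 and AT4G34881, every gene that lost its call under any alternative also lost it without WT replicate 1 or 2.

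UDP-glycosyltransferases, which attach sugars to small molecules, had 33 of 106 genes higher and 6 lower (41 and 7 adjusted over the list alone; camera adjusted p = 0.0234, and adjusted p = 0.791 with an estimated correlation). UGT85A1 rose 11.2-fold, from 10.2 ± 1.87 to 114 ± 39.0 FPKM (3.33 ± 0.24, adjusted p = 0.000608), UGT73C4 rose from 0.321 ± 0.084 to 5.86 ± 2.90, and UGT76E12 from 0.108 ± 0.0754 to 16.0 ± 11.1. The family did not pass without WT replicate 2 (adjusted p = 0.0664, the highest over the alternatives, which began at 0.0109). The 23 families that did not pass had camera adjusted p from 0.0843 (WRKY factors, 15 of 51 higher and 3 lower) to 0.932 (plastid ribosomal proteins). Of these, WRKY factors passed as higher without WT replicate 1 (adjusted p = 0.0261), and WRKY factors, glutathione S-transferases, and chitinases and glucanases without fer-4 replicate 1 (0.0225 each). Cytosolic ribosomal proteins passed as lower at a pseudocount of 5 FPKM (0.0457) and without WT replicate 2 (0.00638).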

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

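The fits without the all-or-none genes, on genes listed in every library and with crossed replicate numbers were chosen after the data were seen; the other alternatives were planned. The count of changed genes stayed within 1.5 times 4469 under each alternative that kept all 4 libraries. Leaving out each library in turn gave 1688 to 4417 genes in all, 1227 to 2681 higher and 461 to 1736 lower, the low values coming from the fits without a WT library, for a cause not tested. The number changed at least 2-fold was 691 at a pseudocount of 5 FPKM, which shrinks the fold changes of low genes, and 886 at a minimum of 5 FPKM, which tests fewer genes. FER stayed lower throughout, with log2 fold changes from -0.57 to -0.53 with a library left out, and was not called without WT replicate 2 (-0.53). Camera called 9 lists and 5 families. With an estimated correlation, and with fry, 0 lists and 0 families were called. These tests also missed the simulated shift of 0.6, made in independent genes. That does not show that they would miss larger shifts, such as the median of 1.31 in the jasmonate response list. Fry did call the dark and sugar starvation list added below (fry adjusted p = 0.00216, adjusted over the added lists alone). That list was drawn up after some of its genes had been seen to rise, so its call does not show what fry can detect in the planned lists. With a library left out the lists called numbered 7 to 10 and the families 5 to 7. No named gene, list or family reversed its direction past a threshold. The cause of the other lost calls was not tested.

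The labels give both genotypes replicates 1 and 2 without saying that a number marks a shared batch. Across genes the replicate differences of the genotypes correlated at -0.22, and 2 pairs are too few to pair the libraries. With the replicate number as a block, 3772 genes were called (2410 higher, 1362 lower), 1360 of them changed at least 2-fold, with FER at -0.55, 10 lists and 5 families; with crossed numbers the block gave 5681 (3315 higher, 2366 lower). Depth limits genes near 1 FPKM, which rest on about 30 fragments, and with 2 libraries per genotype the simulation recovered 61.2% of 1.5-fold changes. That share may be too high for the real libraries, since the simulated spread was more even across genes.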

Other observations

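All lists and tests of this part were chosen after the data had been seen.

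Genes of ER bodies, the endoplasmic reticulum compartments that store beta-glucosidases, and of the jacalin-related lectins that accompany them leaned higher in fer-4. Of 21 tested, 15 rose and 0 fell, 18 and 0 adjusted over the list alone (camera adjusted p = 2.36e-07 over 3 added lists; adjusted p = 0.448 with an estimated correlation; fry adjusted p = 0.0811). All 21 were higher in fer-4 replicate 2 than in replicate 1, with a median of 0.55. BGLU18 rose from 55.4 ± 0.852 to 447 ± 316 FPKM (SD, n = 2; limma, log2 fold change 2.78 ± 0.46, adjusted p = 0.00976) and its neighbour TSA1 from 8.05 ± 0.0106 to 73.2 ± 40.5 FPKM. The lectin genes JAL34 and JAL23 rose 3.09-fold and 18.6-fold, and JAL33 was among the all-or-none genes. JAL33 was also among the largest rises, and BGLU22 stands in the root marker list too. As this list was drawn up after the data were seen, it is not independent evidence of its direction. PYK10 (BGLU23), the main ER body glucosidase of roots, measured 1688 and 1703 FPKM in WT and 2010 and 2328 FPKM in fer-4 and did not pass (adjusted p = 0.198).

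Genes induced by darkness and sugar starvation rose almost as a block. Of 15 tested, 14 rose and 0 fell, 14 and 1 adjusted over the list alone (camera adjusted p = 3e-08; adjusted p = 0.0968 with an estimated correlation; fry adjusted p = 0.00216). Enzymes of branched-chain amino acid breakdown were among them: BCAT2 rose from 0.997 ± 0.129 to 12.9 ± 4.97 FPKM, MCCA from 15.6 ± 1.18 to 37.2 ± 3.38 and IVD from 14.2 ± 0.402 to 26.9 ± 2.93. GDH2, a glutamate dehydrogenase gene, rose 2.95-fold and MIOX4, which oxidises myo-inositol, 11.1-fold. MCCB, the partner subunit of MCCA, measured 37.2 ± 0.611 FPKM in WT and 31.3 ± 0.12 FPKM in fer-4 (adjusted p = 0.0759). ASN1, SEN1 and DIN10 also stand in the starch and sugar list. The list was drawn up after ASN1, SEN1, BCAT2 and MIOX4 had been seen to rise, so it is not independent evidence of its direction.

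The first pattern is the set of 158 all-or-none genes between genotypes that share an ecotype label. A segment of chromosome 3 linked to FER does not account for it: 9.49% of the genes lay within 5 Mb of FER, against 7.7% of all tested genes. Different genetic backgrounds, with the WT libraries farther from the reference genome, stay open: under a rule with the same limit for both genotypes, below 5% in each library of the other, 115 genes were of the fer-4 kind and 17 of the WT kind (87.1% of the fer-4 kind), against 74.7% higher (895 higher, 303 lower) among the other genes called with a change of at least 2-fold, and 85.3% against 72.1% with runs of adjacent genes counted once (Fisher's exact test, p = 0.00181). This counts an excess that had been seen before the explanation was formed, so it does not separate different backgrounds from strong induction in fer-4. Of the 17 WT genes, 7 were listed in neither fer-4 library. A gene listed in neither library may be present but not transcribed. The count therefore does not decide whether only the WT libraries lack reference genes or the lines differ in both directions. Among the 158, 25 pairs lay next to each other among tested genes, against 0 to 4 in the bulk of 10000 random placements. The placements ignore that neighbours can be similar copies that share reads or regulation, as PDF1.2A and PDF1.2C may, so the contrast does not point to a cause. Of the 158, 22.8% were not annotated as protein-coding, against 2.5% of tested genes. Regulation by FER was not tested. Under different backgrounds any call between WT and fer-4, those of the jasmonate and wall genes, MAM1, FLC and FT included, may reflect the lines compared and not the mutation.

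The second pattern is the trace of fer-4-only genes in WT replicate 2. Counting noise would raise either WT library, but among 92 steady genes chosen on the mean of both WT libraries 95.7% were higher in replicate 2. Carry-over of fer-4 RNA or reads would bring along genes that vary between the fer-4 libraries. The 16 such genes had a median excess of -0.92% of the fer-4 replicate 1 level, against 2.93% for the 98 steady genes (permutation test, p = 2e-05, the smallest it can give). The test takes genes as independent, although the 16 include defence genes that varied together, so its p overstates the evidence. The excess also subtracts the WT replicate 1 level, which for some of the 16 was above that in WT replicate 2. It therefore cannot tell a missing trace from a lower level of these genes in the WT replicate 2 seedlings themselves. Of the 16, 5 (GES, PDF1.3, AT2G38240, NATA1 and PDF1.2C) were not listed in WT replicate 2, where carry-over predicts 64.4 fragments in all. A small share of RNA from seedlings that carry these genes without the defence state of fer-4 stays open: 94.9% of the steady genes lay between 1% and 10% of fer-4 replicate 1, but carry-over would fill that band as well, and the band was set after the median had been seen. Against such a share, QQS and 5 more of the 125 genes outside those 16 (AT1G66100, AT1G67148, AT4G13860, AT5G51620 and AT5G53820) lay under 1%, with 9.2 fragments in all where the median share predicts 88.9, but they are too few to exclude it for the set.

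The third pattern is the higher level of defence genes in fer-4 replicate 2 than in replicate 1, where 23 of the 24 jasmonate response genes were higher; over all genes, 161 of 182 over 2-fold apart were higher there, against 32 of 96 between the WT libraries. A difference in scaling does not account for it, since the median over all genes was 0.013 against 0.511 for the jasmonate response list. A larger share of root tissue as the whole cause would raise root markers as much, but their median was 0.16 (interquartile range -0.03 to 0.35). A smaller part stays open, since that median lay above random lists (-0.10 to 0.10) and the shoot markers were at -0.39, below theirs (from -0.09). The random lists, here and below, hold genes drawn singly, so their ranges do not allow for list members that vary together. The root marker BGLU22 also stands in the ER body list, all of whose genes were higher in fer-4 replicate 2. The 13 low-oxygen genes, among them ADH1, LBD41 and HRA1, were higher by a median of 1.35 (random lists, -0.10 to 0.13). ADH1 measured 22.4 FPKM in fer-4 replicate 2 and 5.15 in WT replicate 1. LBD41 and HRA1 measured 62.9 and 29.7 FPKM in fer-4 replicate 2, but 96.2 and 48.2 in WT replicate 1. A low-oxygen state of the seedlings in fer-4 replicate 2, stronger than in fer-4 replicate 1, is a possible explanation. Under it, the jasmonate response list should also follow the low-oxygen genes between the WT libraries. The WT libraries did differ in the low-oxygen genes (-0.81, replicate 2 minus replicate 1). Their jasmonate response list, however, stayed within its random range (-0.08, range -0.11 to 0.05). This goes against such a link in WT, but does not settle the question for fer-4, where both lists were higher in replicate 2. Not set against random lists, the WT medians were -0.11 for jasmonate biosynthesis, -0.12 for ethylene-branch defence, -0.16 for the salicylic acid list and 0.002 for pattern-triggered immunity. Between genotypes 0 of the 13 low-oxygen genes passed by limma, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05. The low-oxygen list did not pass camera (adjusted p = 0.471).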
